A study of Mus musculus with 6 samples.

How the data were processed

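Total RNA of 6 samples of the mouse microglial line BV2 was sequenced from stranded libraries (a directional kit, per the labels' protocols), 3 untreated and 3 exposed to human FL-ApoE4 protein. Per the submitters' processing notes, FastQC 0.11.8, HISAT2 2.2.1, HTSeq and DESeq2 1.30.1 were used with the mouse build GRCm39; the role of each tool and its settings are not given in the sources used here. The strand setting of the counting is likewise not given, so overlapping and antisense genes are uncertain.

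The deposited table of reads holds a normalised signal per gene and library for 40202 genes. Every value was a whole multiple of the smallest value in its column (tolerance 0.01, 100% of values in each library), so whole reads were recovered by division; their totals were 48784016, 53356569 and 54038912 in control replicates 1 to 3 and 45700128, 54965393 and 52034919 in FL-ApoE4 replicates 1 to 3. The authors' deposited tables also give a log2 fold change, a p-value and adjusted p-value per gene, and, for genes over 2-fold, a linear ratio; the column of ratios below 1 holds linear values. The authors' adjusted p was NA for 27305 genes. These tables were used only for the description of the authors' calls. Values are listed at 0 in all libraries for some genes that cells commonly express, so a 0 is reported only as listed at 0. Every per-sample column was mapped to a sample by its name.

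Because the deposited values are normalised, the main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(value + 1), two-sided, for the 14079 genes with a mean normalised value of at least 10 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. Group was the only term, and both groups shared one estimate of spread per gene. The edgeR quasi-likelihood test (4.0.16, TMM) and DESeq2 (1.42.0) were run on the recovered reads as alternatives. Intervals and SEs do not cover differences between cultures that the labels leave unstated.

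Gene lists, 29 of pathways and 8 of cell type markers, were fixed before the data were examined, as were the main test and most alternatives. Lists with at least 5 members past the filter were tested with camera (preset inter-gene correlation 0.01), with an estimated correlation and fry beside it, and members were also counted adjusted over the list alone. Fry tests whether a list moves one way on balance and does not compare it with other genes. Named genes followed a rule set beforehand: the 10 largest changes each way among called genes with non-overlapping libraries or, with none called, the 5 of lowest p each way, said to have missed the threshold; Apoe, Trem2, Tnf, Il1b, Il6, Lrp1 and Abca1, with a further gene that is not reported here; up to 4 members of lowest p in each list; and genes in the authors' tables of changes over 2-fold. Irf1, Nfkbia, Saa3, Lcn2, Acod1, Stk32a, COX1, COX2 and COX3 fall outside that rule and were named after their values were seen.

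The tests were tried on simulated data with the real means, library sizes and 200 changed genes. For the comparison of FL-ApoE4 with control, limma recovered 60% of 1.5-fold, 66% of 2-fold, 96% of 3-fold and 94% of 4-fold changes (50 genes each), with 12 false calls among 170, over 14079 genes. In the same simulation edgeR made 15 false calls among 177 and DESeq2 39 among 202. Simulated genes varied independently, and no simulated library departed across many genes as control replicate 1 did in the real data. These rates therefore do not give the power of the tests on the real libraries. The simulated shifted list was called and 0 other lists were. With independent genes this could not show false list calls that arise from correlated members. In the real data the estimated correlation reached 0.96, in the NF-kB list.

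Alternatives covered the pseudocount (0.5 and 5), the filter (none beyond a mean above 0, and a mean of at least 50), scaling (TMM factors, quantile normalisation, equal totals), limma without trend and with robust variance, a 1.5-fold minimum, a replicate block, and each library left out. Array quality weights, a correction of each library's trend with transcript length and GC content (from GENCODE M21 transcripts, known for 93.3% of tested genes), edgeR, DESeq2 and fry without control replicate 1, and estimated correlations with a library left out were added after the data were seen. The reference given is of build GRCm38 and differs from the authors' build, so no coordinates are printed; it served for transcript length, GC content, gene names (38730 of 40202 names, 96.3%, found among RefSeq symbols of GRCm38.p6) and neighbours. For a single library, a list's median was set against 10000 random lists of equal size matched on mean expression.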

Results

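The series measured total RNA by sequencing in BV2 cells, an immortalised mouse microglial line. A group of 3 samples was left untreated and another group of 3 received human full-length apolipoprotein E4 (FL-ApoE4), the lipid-carrying protein, at 25 µg/ml for 5 h. The labels do not state whether the untreated samples received the vehicle of the protein. Libraries held between 45700128 and 54965393 reads assigned to genes, with a read in 20219 to 20673 of the 40202 listed genes in controls and in 19105 to 19716 with FL-ApoE4. Counting error is therefore small for well expressed genes, and for them the spread between libraries sets the precision. Nothing in the labels says that replicates came from separate cultures grown apart, so p-values measure only the spread between these samples, which may be technical.

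The libraries were not equally alike within a group. Control replicate 1 differed from control replicates 2 and 3 by a chi-square of 77.0 and 86.6 per gene, against 5.54 between control replicates 2 and 3. Among the treated libraries, FL-ApoE4 replicate 1 differed from FL-ApoE4 replicates 2 and 3 by 25.5 and 23.8 per gene, and those differed by 4.93. Its deviations from their mean correlated with transcript length at -0.45 (Spearman, across genes). The same measure was 0.33 in each of FL-ApoE4 replicates 2 and 3, whose reference includes replicate 1, and -0.16 to 0.17 in controls. The first principal component, with 38.5% of the variance, set control replicate 1 apart from the other 5 libraries. Tnf, which encodes a major inflammatory cytokine, was at 44899 normalised reads in control replicate 1 and at 14765 and 13289 in control replicates 2 and 3. The composition of the libraries also differed with the group. The 10 most abundant genes took 5.11% of reads in each control and 5.23% to 5.48% with FL-ApoE4, mitochondrially encoded protein genes 1.67% to 1.70% and 1.74% to 1.77%, and mitochondrial ribosomal RNA genes 0.150% to 0.173% and 0.132% to 0.148%. Libraries of the groups did not overlap in these shares or in the number of genes with a read, which chance gives for 10% of measures with 3 libraries against 3.

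The main comparison asked which transcripts differ after exposure of microglia to the intact protein. No single gene passed the threshold with all 6 libraries. The genes nearest to it are described first. They were picked by their low p, so small spreads and non-overlapping values follow in part from that choice. P2ry6, a receptor for extracellular UDP, was at 883 ± 120 normalised reads in the control group and 2016 ± 180 in the FL-ApoE4 group (mean ± SD, n = 3 each). Cx3cr1, the fractalkine receptor typical of microglia, was at 106 ± 2.51 and 246 ± 30.5. On the lower side, Vegfa, an angiogenic growth factor, was at 3147 ± 179 and 2063 ± 144, and Atf4, a transcription factor of the stress response, at 24574 ± 192 and 18046 ± 1157.

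**Figure D1:**
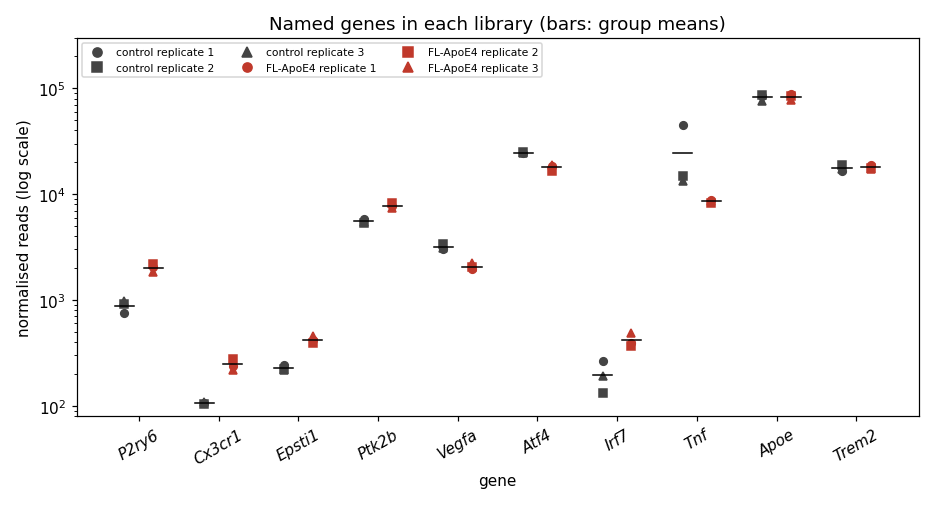
Normalised reads of 10 named genes in each of the 6 libraries on a log axis, with control libraries in grey, FL-ApoE4 libraries in red, marker shapes for replicate numbers and bars for group means. P2ry6 and Cx3cr1 lie higher and Vegfa and Atf4 lower in all 3 FL-ApoE4 libraries, while Tnf has 1 control library at 44899.

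By limma, 0 of 14079 genes reached an adjusted p under 0.05, and 1850 had an unadjusted p under 0.05 (959 higher and 891 lower with FL-ApoE4), where chance alone gives 704. The edgeR quasi-likelihood test called 0 genes and gave 1844 at an unadjusted p under 0.05, whereas DESeq2 called 367. The smallest adjusted p from limma was 0.0666, shared by 11 genes of which 10 were higher. Libraries of the groups did not overlap for 3087 genes (21.9%, where chance gives 10%). The 5 genes of lowest p in each direction, all of which missed the threshold, had log2 fold changes of 1.20 ± 0.12 (SE) for P2ry6, 1.20 ± 0.12 for Cx3cr1, 0.89 ± 0.10 for Epsti1, an interferon-inducible gene, 0.73 ± 0.08 for the predicted gene Gm33103 and 0.49 ± 0.06 for Ptk2b, which encodes a focal adhesion kinase. The corresponding values on the lower side were -0.61 ± 0.07 for Vegfa, -0.45 ± 0.06 for Atf4, -0.73 ± 0.09 for the predicted gene Gm26812, -0.40 ± 0.05 for Cars, the cysteinyl-tRNA synthetase, and -0.50 ± 0.07 for Resf1.

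Leaving out control replicate 1 turned the count from 0 to 651 genes by limma, of which 413 rose and 238 fell. That fit has only control replicates 2 and 3 as controls. They were the most alike controls, at a chi-square of 5.54 per gene against 77.0 and 86.6 for the pairs with control replicate 1. The spread between controls may therefore be understated, and p-values from this fit, here and below, may be too small. Of these, 48 rose and 19 fell by at least 2-fold. P2ry6 (log2 fold change 1.08, limma adjusted p = 0.00064), Cx3cr1 (1.20, adjusted p = 0.00226) and Epsti1 (0.94, adjusted p = 0.00194) were among those that rose. Vegfa (-0.64, adjusted p = 0.00246) and Atf4 (-0.45, adjusted p = 0.00511) were among those that fell. Leaving out FL-ApoE4 replicate 2 gave 1 called gene, the predicted gene Gm33661, and leaving out any of the other 4 libraries gave 0.

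**Figure D2:**
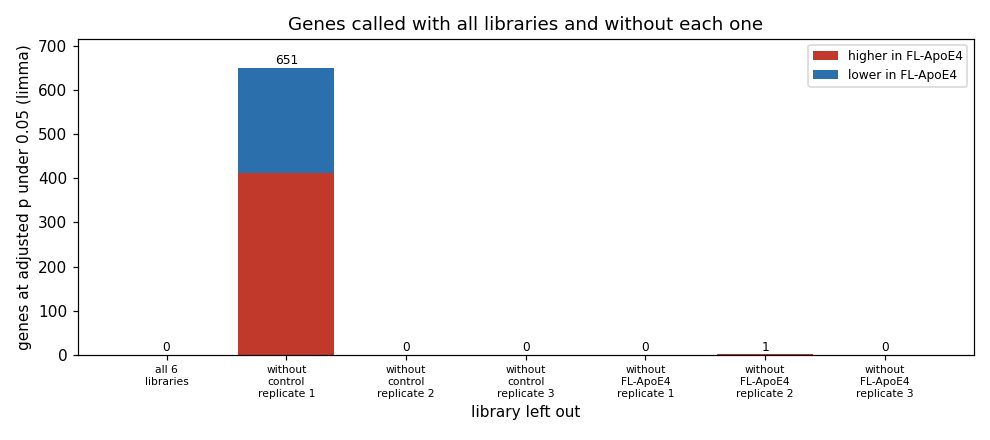
Number of genes at a limma adjusted p under 0.05 with all 6 libraries and with each library left out, stacked by direction (red, higher with FL-ApoE4; blue, lower). Only the bar without control replicate 1, at 651 genes, stands clear of 0, and without FL-ApoE4 replicate 2 there is 1 gene.

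Among genes fixed beforehand for their part in apoE handling, mouse Apoe was at 82216 ± 5018 normalised reads in controls and 83664 ± 5869 with FL-ApoE4, a log2 difference of 0.02 ± 0.07. The lipid-sensing receptor gene Trem2 differed by 0.03 ± 0.07, the receptor gene Lrp1 by 0.21 ± 0.23 and the cholesterol exporter gene Abca1 by -0.24 ± 0.13, each on the log2 scale with its SE. The Abca1 value became -0.07 without FL-ApoE4 replicate 1, and the signs of Apoe, Trem2 and Lrp1 changed between settings. In the list of apoE and lipoprotein receptors, the proteoglycan gene Sdc4 had a log2 fold change of -0.96 ± 0.40 (limma adjusted p = 0.358), and without control replicate 1 it fell by 0.43 (adjusted p = 0.0107). Sort1, which encodes the sorting receptor sortilin, had 0.49 ± 0.14 (adjusted p = 0.216). Tnf was lower by 1.27 ± 0.41, with a limma adjusted p of 0.261 over all 6 libraries, and fell by 0.71 without control replicate 1 (adjusted p = 0.000841). Il1b and Il6 are listed at 0 in all 6 libraries, as is B2m, which cells commonly express.

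Gene lists were tested for a joint shift. Of 31 lists, 15 shifted by camera with a preset correlation of 0.01, 6 higher and 9 lower with FL-ApoE4. None held with an estimated correlation, where the smallest adjusted p was 0.301. Fry called 5, the immediate early, amino acid response, complement and phagocytosis, G2/M, and monocyte and macrophage lists. It did not call the interferon (fry adjusted p = 0.163), resting microglia (0.104), cholesterol (0.163), NF-kB (0.518) or cytokine (0.553) lists, among others. Over all genes 0 members of any list were called by limma (1850 of all genes had an unadjusted p under 0.05, and edgeR called 0), so counts of members below are those adjusted over the list alone. Without control replicate 1 camera called 11 lists, 10 of them among the 15, and fry called 1, the immediate early genes (adjusted p = 0.0379).

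Type I interferon response genes, which are induced by antiviral signalling, shifted higher, with a median log2 fold change of 0.57 over 31 measured members (camera adjusted p = 1.16e-09, adjusted p = 0.445 with an estimated correlation). Positive values were seen in 28 members. Adjusted over the list alone, 13 rose and 1 fell. Oas2, an antiviral RNA sensor, was at 321 ± 111 normalised reads in controls and 701 ± 169 with FL-ApoE4, and Irf7, the transcription factor that amplifies interferon output, at 195 ± 65.2 and 417 ± 63.2. Usp18, a brake on interferon signalling, was at 24.7 ± 1.49 and 55.3 ± 13.2. The member that fell was Irf1 (log2 fold change -1.07), a gene named here because it was the exception. In this list control replicate 1 lay 0.79 (log2, median) above the other controls, and without it 19 members rose and 1 fell over all genes, with a median of 0.94 and a log2 fold change of -0.67 for Irf1 (adjusted p = 2.55e-22 by camera and 0.348 with an estimated correlation). Without control replicate 2 or 3 the median was 0.32 or 0.38.

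Genes of resting microglia also shifted higher, by a median of 0.24 over 17 members (adjusted p = 1.8e-05 by camera and 0.366 with an estimated correlation). Of them 8 rose, adjusted over the list alone, among them Cx3cr1 and Irf8, a transcription factor of the myeloid lineage (log2 fold change 0.48 ± 0.12). Csf1r, the receptor for the growth factor on which microglia depend, belongs to this list and to that of monocytes and macrophages and was at 47193 ± 1926 and 55105 ± 2509 normalised reads. The monocyte and macrophage markers shifted by a median of 0.19 over 8 members (camera adjusted p = 0.00278, adjusted p = 0.308 with an estimated correlation), and 2 rose adjusted over the list alone, Csf1r and Adgre1 (log2 fold change 0.35 ± 0.06), which encodes the surface protein F4/80. Control replicate 1 lay 0.23 below the other controls (log2, median) in the resting microglia list. Without that library camera called both lists (adjusted p = 6.2e-05 and 0.00176), with an adjusted p of 0.348 for each with an estimated correlation.

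Immediate early genes, which respond within minutes to hours to growth factor and stress signals, shifted lower by a median of -0.50 over 23 members (camera adjusted p = 3.72e-11, adjusted p = 0.301 with an estimated correlation). Adjusted over the list alone 12 fell and 0 rose by limma. Junb, an AP-1 subunit, was at 16585 ± 2659 normalised reads in controls and 10870 ± 501 with FL-ApoE4. Nr4a1, an orphan nuclear receptor, was at 1143 ± 347 and 514 ± 147, and the phosphatase gene Dusp2 had a log2 fold change of -0.50 ± 0.10. Without control replicate 1 the list's median was -0.33 (adjusted p = 7.3e-11 by camera and 0.348 with an estimated correlation), with 10 members called lower over all genes.

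Genes of the ATF4 amino acid response, through which cells restore amino acid supply, were lower in 21 of 21 members, with a median of -0.21 (camera adjusted p = 1.2e-12, adjusted p = 0.301 with an estimated correlation). Of these, 13 fell adjusted over the list alone. Chac1, a glutathione-degrading enzyme, was at 141 ± 21.4 and 48.7 ± 16.6 normalised reads. Ddit4, an inhibitor of mTORC1, was at 461 ± 137 and 173 ± 41.9, and Sesn2, a leucine sensor, at 2944 ± 460 and 1508 ± 263. The unfolded protein response list shares members with the amino acid list, Chac1 and Trib3 among them. It had a median of -0.01 (adjusted p = 0.034 by camera and 0.366 with an estimated correlation). Adjusted over the list alone 4 of its members fell, Atf4, Chac1, Herpud1 and Trib3. The call of the unfolded protein response list was lost without control replicate 1, control replicate 2 or FL-ApoE4 replicate 2 (camera adjusted p = 0.0951, 0.063 and 0.0631). It was also lost with quantile normalisation (0.115) and with a mean of at least 50 (0.0516). The camera adjusted p of the amino acid list was at most 6.52e-11 in these settings.

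The NF-kB and Toll-like receptor early response shifted lower by a median of -0.43 over 28 members (camera adjusted p = 1.83e-05, adjusted p = 0.622 with an estimated correlation), and 6 fell adjusted over the list alone. Nfkbiz, an atypical IκB protein, was at 6214 ± 2563 normalised reads in controls and 2128 ± 190 with FL-ApoE4. Nfkbia, which encodes IκBα, had a log2 fold change of -0.88 ± 0.23, and of -0.58 without control replicate 1. Inflammatory cytokines and chemokines shifted by a median of -0.80 over 17 members (adjusted p = 0.00367 by camera and 0.622 with an estimated correlation), and Tnfsf9 alone fell adjusted over the list. Both calls rested on control replicate 1, in which the lists lay 1.12 and 1.68 (log2, median) above the other controls. Without it the medians were -0.03 and -0.12 (camera adjusted p = 0.664 and 0.461), with 8 members of the NF-kB list called higher and 11 lower over all genes.

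**Figure D3:**
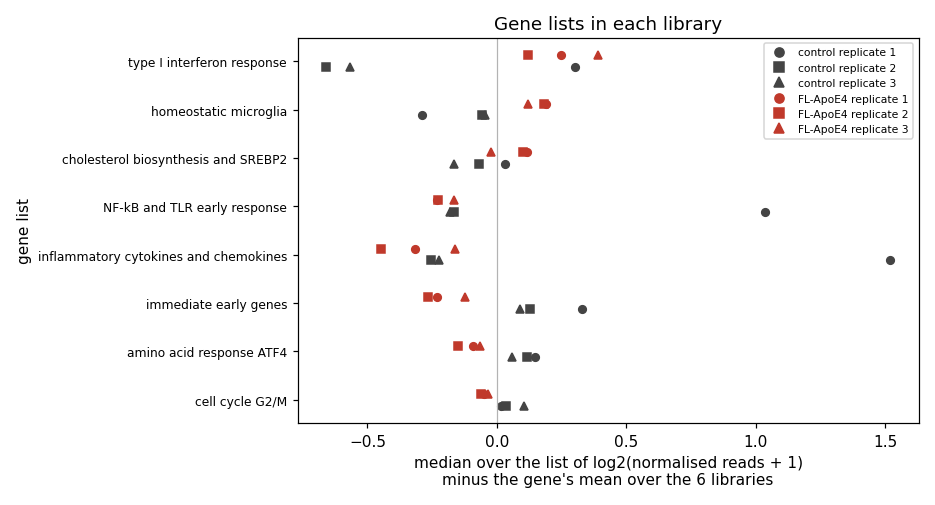
Median over each of 8 gene lists of the log2 value in a library minus the gene's mean over the 6 libraries (x axis), with control libraries in grey and FL-ApoE4 libraries in red. The 3 FL-ApoE4 libraries lie below all controls for immediate early genes and the amino acid response, while control replicate 1 lies far to the right of every other library for the NF-kB and cytokine lists.

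The medians of proliferation genes and, as a separate list, of p53 targets and apoptosis genes shifted lower by small amounts. The G2/M list had a median of -0.11 with 23 of 25 members negative (camera adjusted p = 1.03e-07, adjusted p = 0.308 with an estimated correlation), and 3 fell adjusted over the list alone. Ccnb1, the mitotic cyclin B1, was at 8518 ± 464 and 7283 ± 171 normalised reads. The G1/S list had a median of -0.08 (adjusted p = 1.83e-05 by camera and 0.472 with an estimated correlation), and Cdc45, a subunit of the replicative helicase, fell adjusted over the list alone (log2 fold change -0.27 ± 0.05). Replication-dependent histones had a median of -0.22 over 11 members, all negative (adjusted p = 0.00845 by camera and 0.445 with an estimated correlation), with 0 called over the list alone by limma. The p53 and apoptosis list had a median of -0.08, at an adjusted p of 0.0109 by camera and 0.366 with an estimated correlation. Adjusted over the list alone 5 members fell, Gdf15, a stress cytokine, among them (log2 fold change -1.74 ± 0.37). This list shares Sesn2 with the amino acid list and Btg2 with the immediate early genes. The call of the p53 list was lost without control replicate 1 (adjusted p = 0.0531, median -0.02) and that of the histones without control replicate 2 or FL-ApoE4 replicate 2 (0.0768, with a median of -0.10, and 0.0624). Among medians that stayed called, that of G1/S was -0.12 without control replicate 1, that of p53 was -0.13 and -0.15 without FL-ApoE4 replicates 1 and 2, and that of the histones was -0.39 without FL-ApoE4 replicate 3.

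Lipid and complement genes shifted by small amounts. Cholesterol biosynthesis genes shifted higher by a median of 0.13, with 21 of 22 members positive (camera adjusted p = 6.85e-05, adjusted p = 0.472 with an estimated correlation), and 0 members passed limma adjusted over the list alone. Mvd, of the mevalonate pathway, had a log2 fold change of 0.33 ± 0.09. The list of targets of the sterol sensor LXR and of cholesterol efflux shifted by a median of 0.10 (adjusted p = 0.0265 by camera and 0.445 with an estimated correlation). Of its 17 members 13 were positive and 4 negative. Nr1h3, which encodes LXRα, and Abcg1, a cholesterol exporter, rose adjusted over the list alone (log2 fold changes 0.27 ± 0.06 and 0.55 ± 0.14). Abca1, another exporter in the list, was among the negative members (-0.24 ± 0.13), and Apoe, also a member, was at 0.02 ± 0.07. Complement and phagocytosis genes shifted by a median of 0.07 (adjusted p = 0.0265 by camera and 0.308 with an estimated correlation). The LXR call was lost without control replicate 1 or FL-ApoE4 replicate 2 (adjusted p = 0.332, with a median of 0.04 and 10 of 17 members positive, and 0.107), and the complement call without FL-ApoE4 replicate 2 (0.0631). The complement median was 0.13 without control replicate 1, and without control replicate 3 the cholesterol and LXR medians were 0.06 and 0.18. A correction for transcript length and GC content ended the LXR and complement calls (adjusted p = 0.0949 and 0.0691) and that of the unfolded protein response (0.0691).

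The other 16 lists were not called by camera. Disease-associated microglia genes, a set of which Apoe and Trem2 are members, had a median log2 fold change of 0.04 (adjusted p = 0.0918, and 0.0354 without FL-ApoE4 replicate 3, where an estimated correlation gave an adjusted p of 0.436), and Igf1 and Cd52 rose adjusted over the list alone (0.28 ± 0.05 and 0.30 ± 0.06). Antigen presentation had a median of 0.11 (adjusted p = 0.224), with Tap1, of the peptide transporter, rising adjusted over the list alone (0.30 ± 0.05), and without control replicate 1 the list was called (adjusted p = 0.00034 by camera and 0.348 with an estimated correlation). Glycolysis and hypoxia had a median of 0.00 (adjusted p = 0.677), and adjusted over the list alone Vegfa, Pfkp and Hilpda fell and Pfkfb3 rose. The remaining camera adjusted p values were 0.943 for apoE and lipoprotein receptors, 0.986 for alternative activation, 0.314 for inflammasome, 0.607 for lysosome and autophagy, 0.943 for NRF2, 0.607 for heat shock, 0.858 for nuclear oxidative phosphorylation, 0.751 for mitochondrially encoded transcripts, 0.986 for ribosomal proteins, 0.0957 for noncoding RNAs, 0.133 for actin and adhesion and 0.943 for the TGF-beta response. Endothelial markers had an adjusted p of 0.201, with Flt1 rising adjusted over the list alone. Without FL-ApoE4 replicate 1 the endothelial list was called higher (adjusted p = 0.0171), and the ribosomal protein and oxidative phosphorylation lists were called lower (0.00311 and 0.0373). With an estimated correlation these adjusted p values were 0.431, 0.639 and 0.621. Median, mean and test differed in sign for alternative activation, NRF2, mitochondrial transcripts, apoE receptors, the TGF-beta response and the inflammasome list.

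Most markers of other cell types were below a mean of 10 normalised reads, but some were abundant. Of 10 endothelial markers 5 reached that mean, with means over the 6 libraries of 5715 for Flt1, 4179 for Kdr and 1260 for Vwf. The astrocyte marker Aldoc was at 2871, and the oligodendrocyte markers Mbp and Cnp were at 1121 and 767. Of 10 markers each, 3 of astrocytes, 2 of neurons, 3 of oligodendrocytes, 1 of fibroblasts or pericytes, 4 of lymphocytes and 1 of neutrophils reached a mean of 10 normalised reads, too few for a test of those lists.

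The authors' deposited table of significant genes holds 367 genes, 195 higher and 172 lower with FL-ApoE4. All 367 had the same direction in the limma fit, and 0 passed its threshold (366 had an unadjusted p under 0.05 in that fit). The edgeR test called 0 genes of all. DESeq2 on the recovered reads called these same 367 genes, so its count is not independent of the authors' table. Of the 367 genes, 279 were called by limma without control replicate 1. Over 2-fold changes in the authors' deposited table numbered 20 higher and 28 lower. Among the higher genes were P2ry6 at a ratio of 2.28, Cx3cr1 at 2.32 and Siglece, an inhibitory receptor for sialic acids, at 2.35, each with libraries that did not overlap. The largest ratio in the authors' deposited table was 154 for the predicted gene Gm33661, with normalised reads of 2036, 5.56 and 860 in the FL-ApoE4 libraries and 4.71 to 7.59 in controls. Pcsk5, a proprotein convertase gene, followed at 22.5, with 1023, 380 and 9.79. The largest reduction in the authors' deposited table was a ratio of 0.176 for the cytokine gene Il27, which had no limma call with or without control replicate 1 (log2 fold change -1.94 and -1.08, adjusted p = 0.292 and 0.132) and was at 161 normalised reads in that library against 25.6 and 27.3 in the other controls. ATP6, at a ratio of 0.436 in the authors' deposited table, is uncertain, as its libraries overlapped and its level of 200.4 ± 78.9 normalised reads in controls and 87.6 ± 24.7 with FL-ApoE4 lay far below that of COX1, another mitochondrial transcript, at 240411 ± 3178 and 252256 ± 5723. ATP8, COX2 and COX3 were likewise far below COX1, with control means of 28.6, 108 and 97.7, for a reason that is not known here.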

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

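Array quality weights, the length and GC correction, edgeR, DESeq2 and fry without control replicate 1, and estimated correlations with a library left out were chosen after the data were seen. The count of genes called by limma with all 6 libraries (0, with 1850 at an unadjusted p under 0.05, edgeR calling 0 and DESeq2 367) stayed at 0 with pseudocounts of 0.5 and 5, a mean of at least 50, TMM factors, quantile normalisation, equal totals, no trend, robust variance, a 1.5-fold minimum and the length and GC correction. With no filter beyond a mean above 0 it was 1 (P2ry6), and with array quality weights 1551; the cause was not tested, nor that of the difference to DESeq2. Leaving out each library gave 0 to 651 genes by limma, the highest without control replicate 1 and 1 without FL-ApoE4 replicate 2. Without control replicate 1, edgeR called 691 genes, DESeq2 903 and limma after the length and GC correction 1325, of which limma without correction shared 645 with edgeR and 623 with DESeq2. Of the authors' 367 genes limma with all libraries called 0, also when kept to those with a mean of at least 50, but 1 with no filter beyond a mean above 0 and 361 with array quality weights. With the replicate block limma called 0 genes (2177 at an unadjusted p under 0.05), and camera called 14 lists, 13 of them among the 15. The LXR and unfolded protein response lists were not called with the block (adjusted p = 0.0662 each) and disease-associated microglia was (0.0483). Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated across genes at 0.22, 0.16 and -0.02. FL-ApoE4 replicate 2 correlated best with control replicate 3 (0.32), but control replicate 1 correlated best with FL-ApoE4 replicate 1. Each of these latter libraries was the least like the others in its group and had the fewest reads there. Their deviations correlated with transcript length at -0.16 and -0.45. These correlations cannot exclude handling shared by number.

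The 15 lists called by camera became 0 with an estimated correlation, with all libraries and with each library left out, and 5 by fry (1 without control replicate 1); the cause was not tested. Other settings gave 14 (quantile normalisation), 13 (a mean of at least 50) and 12 (length and GC correction), and leaving out each library gave 11 to 18. Of the lists called with all libraries, only the NF-kB list changed the direction of its test in a setting run, by fry without control replicate 1 (uncalled, adjusted p = 0.766, with a median of -0.0297, and -0.616 to -0.0297 over the left-out libraries); the cause was not tested. Without FL-ApoE4 replicate 1, the ribosomal protein and oxidative phosphorylation lists were called lower after a positive, uncalled median. Their medians there were -0.0526 (-0.0526 to 0.0502 over the left-out libraries) and -0.0369 (range -0.0369 to 0.0486). In FL-ApoE4 replicate 1 these lists lay at 0.12 and 0.11 against each gene's mean over the 6 libraries. That library's deviations from the other treated libraries correlated with transcript length at -0.45 (Spearman). Whether this trend moved the lists was not tested. Acod1 went from an uncalled -0.28 to a called 0.63 without control replicate 1 by limma, edgeR and DESeq2, and 0.61 with the length and GC correction (-0.74 to 0.63 over the left-out libraries); the cause was not tested. Of 1530 values of 67 named genes under other settings, 36 had another sign, in 10 genes (Acod1, Apoe, Cnp, COX1, Kdr, Lcn2, Lrp1, Stk32a, Trem2 and Vwf). Scalings moved the median of all genes to at most 0.02 on the log2 scale. Depth limits low genes most: 24244 genes had a mean above 0 and 14079 a mean of at least 10.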

Other observations

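All tests in this part were chosen after the first results were seen, except the splits of all 6 samples; the bounds of the equal-depth and length and GC tests and of the position of control replicate 1 over the called genes were set before their own results, and that of the neighbouring-gene test was set so for the highest library and extended afterwards. Control replicate 1 departed from the other controls in several lists, with the largest medians in those of inflammation. Its cytokine list lay 1.68 higher on the log2 scale in the median (17 of 17 members), its NF-kB list 1.12 (28 of 28) and its interferon list 0.79 (29 of 31), each above all 10000 random lists matched on expression, as a description of this library. The lists of antigen presentation (0.42, 13 of 14 members), immediate early genes (0.24, 15 of 23), NRF2 (0.22, 17 of 20) and cholesterol biosynthesis (0.18, 18 of 22) also lay above all 10000, while the resting microglia list, at -0.23, lay at percentile 0.06. Cxcl2, a neutrophil chemokine gene, was at 18471 normalised reads in it and at 3112 and 2711 in the other controls. Acod1, which makes itaconate, was at 41246 against 6217 and 6257.

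Against control replicates 2 and 3, the interferon list of the FL-ApoE4 libraries lay 0.94 higher and their NF-kB list at -0.03. Set against each gene's mean over the 6 libraries, the interferon list lay at 0.25, 0.12 and 0.39 in FL-ApoE4 replicates 1 to 3 and at 0.30 in control replicate 1, within their range. Within the NF-kB list 8 members were called higher by limma without control replicate 1 and 11 lower. The acute-phase genes Saa3 (log2 fold change 1.41) and Lcn2 (1.17) and the gene Acod1 (0.63) rose in that fit, while Nfkbiz (-1.16) and Nfkbia (-0.58) fell. In the cytokine list 2 members were called higher in that fit and 5 lower, Tnf (-0.71) and Cxcl2 (-1.36) among the lower ones.

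The first pattern weighed is that more genes were called when control replicate 1 was left out. Depth was argued against by the totals, since control replicate 1 held 48784016 reads and FL-ApoE4 replicate 1, the shallowest, 45700128. With all libraries thinned to that lowest total limma still called 0 genes with all 6 (1784 at an unadjusted p under 0.05). It called 634 without control replicate 1. On unthinned reads edgeR called 0 and DESeq2 367. Thinning removed few reads, so this test alone could hardly have come out otherwise. After removal of trends with transcript length and GC content limma also called 0 (2039 at an unadjusted p under 0.05). For a treated sample under a control label, the NF-kB list lay 1.12 above the other controls in control replicate 1. It lay between -0.05 and -0.03 in the 3 FL-ApoE4 libraries, so control replicate 1 was unlike them in this list. That test was chosen afterwards, on a list in which this library stood out, so it cannot decide the question. It replaced the one set beforehand, the median position of control replicate 1 from the other controls (0) to the FL-ApoE4 mean (1) over the 651 genes. That position was 0.47 with quartiles of -0.49 and 1.21 and decides nothing. On the FL-ApoE4 side lay 425 genes and on the other 226. The median position was 0.73 for genes higher with FL-ApoE4 and 0.15 for lower ones. A treated sample under a control label, a sample from outside the series or a culture activated before harvest stays open. No biological explanation was tested, since the design names none.

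The second pattern is the higher interferon list with FL-ApoE4. Its camera adjusted p ranged over all settings from 2.55e-22, without control replicate 1, to 0.621, with an estimated correlation and without control replicate 3. A trend with transcript length or GC content was argued against, because the median of 0.57 became 0.60 after its removal. Endotoxin carried with the protein could raise interferon genes and cannot be told apart from the protein's own effect: the controls are untreated, and the 8 higher and 11 lower members of the NF-kB list go both ways. An effect of FL-ApoE4 itself remains open beside it.

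The third pattern is that Gm33661 and Pcsk5, at the top of the authors' table, were each high in 2 of 3 FL-ApoE4 libraries (replicates 1 and 3 for Gm33661, 1 and 2 for Pcsk5), with the third below the highest control. Reads from an active neighbour were argued against, because in each library where a gene was high its neighbours with a mean of at least 10 lay at no more than 1.22 times their mean in the libraries where it was not. An effect of FL-ApoE4 in some cultures stays open and untested. A candidate explanation also left open is that cultures differ in subclones, as a range of at least 8-fold within a group (after adding 10 to each value) was met by 3 genes among controls and 6 among FL-ApoE4 libraries, Stk32a (343 in control replicate 3 and 384 in FL-ApoE4 replicate 2, at most 27.5 elsewhere) among both.

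With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For the limma count the real split gave 0 (1850 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 367) and the highest other split 0, so all 10 gave as many. For the DESeq2 count, 1 of 10 splits gave as many as the real 367, and the highest other gave 10. For the camera count, 2 of 10 splits gave at least the real 15 lists. The highest other, which set control replicates 1 and 3 with FL-ApoE4 replicate 1 against the rest, gave 18. The lowest other split still gave 4 lists. Without control replicate 1, the real split of 2 against 3 libraries gave 651 genes and the highest other 2, with 1 of 10 splits giving as many.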
